A study of Mus musculus with 9 samples.

How the data were processed

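Single-cell suspensions of pancreatic islets from NOD/ShiltJ mice aged 8, 14 and 16 weeks were measured with the 10X Genomics droplet assay, in which each cell receives a barcode and each captured transcript a unique molecular identifier (UMI). There were 9 libraries, 3 per age, and each age had replicate letters A, B and C. Per the labels' protocols, cells carrying CD45, the surface protein of white blood cells, were depleted before the libraries were made. The labels name no batch, date or sequencing lane, and no animal, so p-values over the 3 libraries of an age measure the spread between these libraries.

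The values used are UMI counts per gene and cell, deposited by the authors as raw whole numbers with no normalization. Cell Ranger 2.0.0 and the genome build mm10 are named per the submitters' processing notes. The gene annotation behind the counts, the settings for calling cells and the sequencing depth in reads are not given in the sources used here. The matrices listed 27998 genes, the same in each library. Each library's smallest cell held between 3990 and 7185 UMIs, so the cells had passed a UMI minimum that differed between libraries. That minimum was 7005 in 16 weeks B and 7185 in 16 weeks C, against 4510 in 16 weeks A and 3990 to 5108 at the earlier ages. In 8 weeks B the barcode list had 2238 lines and the matrix 2673 cells, so cells were taken by their place in the matrix, and barcodes were not used. Gene positions came from GENCODE release M21 on GRCm38, the same assembly as mm10, which held 27722 of the 27998 gene identifiers.

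The matrices held 32673 cells in all. Cells with at least 500 genes and at most 20% mitochondrial UMIs were kept. Scrublet was run on each library and its calls were removed, which left 31840 cells. It marked 160 cells, or 0.5%. The expected rate of 0.8% per 1000 cells came to between 2.06% and 4.00% of the cells of a library. In 14 weeks A it marked 0.08% against 4.00% expected, and in 8 weeks A 2.11% against 2.31%. Doublet removal was thus of little effect, and doublets may remain. Counts per cell were scaled to a fixed total and log transformed. Clusters were made from 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). Clusters that could not be named and held at least 60 cells were clustered once more by themselves and named by the same rule, giving 93 clusters. Clusters were named "X-like" from fixed marker genes of 21 cell types. A cluster with fewer than 3 detected markers, with leading genes of another class or with a second class at 0.6 or more of the first class's level was left unnamed. These naming thresholds were set after clustering. The limit on markers of another class (a median of 75% of cells) and an exception for endothelial markers in lymphatic endothelial cells were set after first names had been seen.

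Raw counts were summed per library and class, with at least 20 cells per sum. Age was tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr, and a robust quasi-likelihood fit with age as a factor over all 9 libraries. P-values were adjusted by the Benjamini-Hochberg method, and genes under 0.05 are counted. Levels are in CPM, TMM-scaled counts relative to the library total. The difference of the 16 v 8 week change between beta-like and alpha-like cells was an interaction term with the library as a block. Cells with and without a Cdkn1a UMI were compared within libraries on counts thinned to 14000 UMIs per cell, with the library as a block and Cdkn1a left out. For 28 fixed gene lists, camera (limma 3.58.1) was run with a preset correlation of 0.01 and again with an estimated one. Members past the threshold were counted over all genes tested and adjusted over the list alone. Class shares and shares of cells with a UMI were compared by 2-sided exact permutation over the 280 splits of 9 libraries into 3 ages. For 2 ages the smallest p that exact permutation allows is 0.1. Intervals on shares are exact binomial at 95% and cover counting error.

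The tests, samples, markers, lists, alternatives and the rule for named genes were set before the data were examined, except those stated below as chosen or added afterwards. For each pair of ages in beta-like cells the rule took the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 20 CPM, no overlap between the libraries of the 2 ages, and no sign of free RNA. It left out predicted genes, pseudogenes, receptor segments, Xist and Y-linked genes. It added up to 4 members of each list by p, and 19 fixed genes of senescence, insulin production and interferon response. Other classes, the interaction and the Cdkn1a comparison used 5 and 5. Some genes that the rule takes are not reported here. A gene counted as possible free RNA where its level in a class was under 0.1 of that in another class, where it was a hormone of another islet class, or where it was on the acinar list. Genes with at least 50% of the last 300 bases of a transcript shared, in 50-base words, with another gene were marked as sharing their 3′ end, since the assay reads 3′ ends.

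The steps were tested on simulated data with 200 changed genes. For 16 v 8 weeks in beta-like cells, over 11612 genes, edgeR recovered 23.9% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 95.5% of those changed 4-fold, and 6 of 126 calls (4.76%) were false. For pericyte-like cells, over 5337 genes, the shares were 0%, 13.4% and 68.2%, with 2 of 56 calls false. For the interaction, over 12840 genes, they were 17.9%, 53.7% and 86.4%, with 8 of 113 calls false. For the Cdkn1a comparison, over 7639 genes, they were 76.1%, 89.6% and 89.4%, with 14 of 184 calls false. False calls were more frequent for edgeR in alpha-like cells at 16 v 8 weeks, with 14 of 135 (10.4%). The same held for DESeq2 in beta-like cells at 16 v 8 weeks, with 15 of 132 (11.4%). A simulated list of 15 changed genes was called by camera, and 0 of 28 unchanged lists were. Simulated genes were drawn independently, so this cannot show how often lists of correlated genes are falsely called. In beta-like cells the estimated correlation was 0.967 for MHC class I genes and 0.924 for interferon response genes.

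Alternatives covered the scaling, the tool (DESeq2 1.42.0 and limma-voom), filters on genes and cells, doublets, clustering, thinning, cell numbers, hormone genes, the replicate letter as a block, and each library left out in turn. Another 4 were added after the data were seen: the highest doublet scores left out up to the expected rate, 16 weeks A and 8 weeks C left out together, genes sharing their 3′ end left out of counts, and, for the Cdkn1a comparison, cells thinned to 5500 UMIs other than those of Ins1 and Ins2, which were thinned by the same share. Immune, acinar, Schwann and lymphatic endothelial cells had too few cells in some libraries for tests of single genes.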

Results

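Islets of NOD mice, a strain in which autoimmune diabetes arises spontaneously, were profiled by droplet single-cell RNA sequencing at 8, 14 and 16 weeks of age, with 3 libraries per age. The series title concerns senescent beta cells, so the questions were which transcripts differed with age in beta cells and where marks of senescence stood. Total UMIs were 34866615, 28643128 and 38741926 in libraries A, B and C at 8 weeks, 67622971, 56714807 and 35653274 at 14 weeks, and 53252317, 66731640 and 63931146 at 16 weeks. The median cell held 8022.5, 7536 and 7313 UMIs at 8 weeks, 9319.5, 9991 and 7682 at 14 weeks, and 7950.5, 13703 and 15223 at 16 weeks. Libraries B and C at 16 weeks were thus deeper per cell than the rest and had a higher UMI minimum. Nothing in the labels separates library batch from age, so batch and age cannot be told apart.

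Of 31840 cells, 6852 were alpha-like, 6384 delta-like, 4832 fibroblast-like, 4041 beta-like, 3400 ductal-like, 1285 gamma-like, 1221 endothelial-like and 537 pericyte-like. The immune cells left after CD45 depletion were 491 dendritic-like, 203 T-like, 141 macrophage-like, 102 B-like and 49 plasma-like cells. Clusters of endocrine cells separated by age. Most beta-like cells at 8 weeks lay in cluster 16, at 14 weeks in cluster 7 and at 16 weeks in cluster 9, and alpha-like, delta-like and gamma-like cells separated likewise, as did part of the ductal-like and fibroblast-like cells. Unnamed clusters, mostly of mixed markers, held 4.28% of cells at 8 weeks, 6.06% at 14 weeks and 7.15% at 16 weeks.

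Immune cells of named classes made up 0.420% ± 0.316 of cells at 8 weeks, 5.01% ± 1.26 at 14 weeks and 4.22% ± 5.41 at 16 weeks (SD, n = 3 per age). Here and below, shares of immune cells leave out unnamed clusters with immune markers, such as cluster 18.2, with 71 cells of mixed T and B markers. By library, the share was 0.283%, 0.782% and 0.196% at 8 weeks, 4.69%, 3.96% and 6.40% at 14 weeks, and 0.0404%, 2.29% and 10.3% at 16 weeks in A, B and C. Library A at 16 weeks thus had the lowest share of the 9. Acinar-like cells, which make digestive enzymes, were 0.0826% ± 0.0647, 0.214% ± 0.131 and 0.896% ± 0.212 of cells at the 3 ages (adjusted p = 0.129, exact permutation test). Beta-like cells were 7.11% ± 1.01, 14.2% ± 5.69 and 16.8% ± 9.38 (adjusted p = 0.336, exact permutation test). No class share passed adjustment, though acinar-like (p = 0.00714) and pericyte-like cells (p = 0.0429) and the unnamed share (p = 0.0464) had lower unadjusted exact permutation p-values. CD45 depletion and the freeing of cells from tissue can set these shares, as can the UMI minimum.

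At 16 weeks, beta-like cells had lower transcripts of immediate early and stress genes and higher transcripts of part of the beta cell identity genes, 12 of 23, than at 8 weeks. As lists, they passed with the preset correlation of camera (adjusted p = 7.66e-15 and 0.00231) but not with an estimated one (adjusted p = 0.257 and 0.470), with which 0 of 84 list tests in beta-like cells were called. Nr4a1, an immediate early transcription factor, stood at 176 ± 25.7 CPM at 8 weeks and 20.8 ± 3.50 CPM at 16 weeks (SD, n = 3), a log2 change of -3.09 ± 0.19 (SE; adjusted p = 1.94e-06). Dnajb1, a heat shock co-chaperone, went from 244 ± 10.5 to 36.5 ± 4.09 CPM (log2 change -2.75). Pdx1, a transcription factor that maintains beta cells, went from 29.3 ± 3.23 to 51.6 ± 4.68 CPM, a log2 change of 0.81 ± 0.11 (adjusted p = 0.000154). Of 11612 genes tested, 1563 were higher and 1704 lower at 16 weeks, 3267 in all. On GRCm38, Nr4a1 (ENSMUSG00000023034) lies on chromosome 15 from 101254269 to 101274795, Pdx1 (ENSMUSG00000029644) on chromosome 5 from 147269959 to 147275848, Cdkn1a (ENSMUSG00000023067) on chromosome 17 from 29090976 to 29100727 and B2m (ENSMUSG00000060802) on chromosome 2 from 122147686 to 122153083, all on the plus strand. The plot of levels by library shows Nr4a1, Dnajb1, Pdx1, Iapp, B2m and Cdkn1a.

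**Figure D1:**
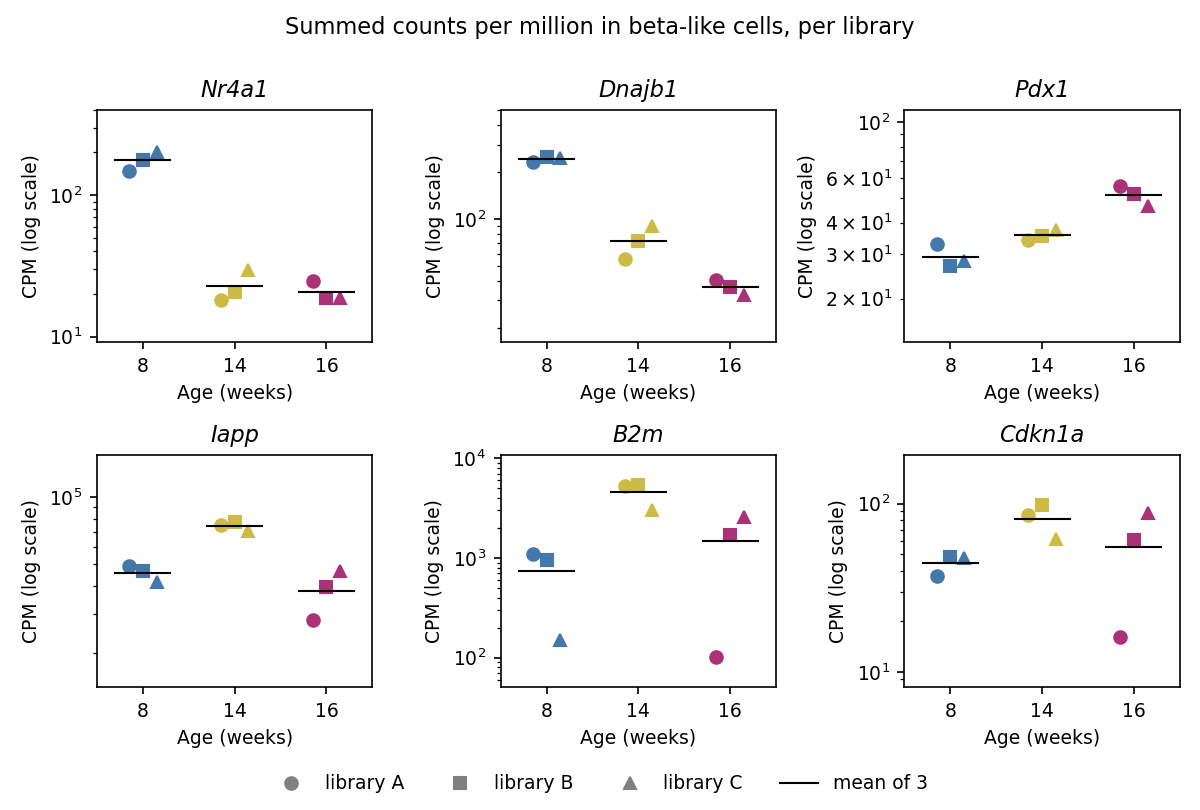
Levels in beta-like cells of 6 genes by age in weeks, in CPM on a log axis, with a point per library (circle A, square B, triangle C) and a black line at the mean of 3 libraries. Nr4a1 had a mean of 176 CPM at 8 weeks and 20.8 CPM at 16 weeks, while B2m varied between libraries of an age, from 101 to 2594 CPM at 16 weeks.

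Among 23 genes of beta cell identity and glucose sensing, 12 rose and 0 fell at 16 v 8 weeks over all genes tested, and 12 rose adjusted over the list alone (camera adjusted p = 0.00231; adjusted p = 0.470 with an estimated correlation). Nkx6-1, another identity factor, rose by 0.88 ± 0.12 on the log2 scale (SE), Slc2a2, the glucose transporter of mouse beta cells, by 0.84 ± 0.17, and Ero1lb, an oxidoreductase for insulin folding, by 0.50 ± 0.08. Mafa, an activator of insulin transcription, rose by 1.96 ± 0.48 at a low level, from 0.398 to 1.75 CPM. Ins1 rose by 0.28 ± 0.06 (adjusted p = 0.00406), while Ins2 changed by -0.03 and did not pass. Of 13 immature or disallowed genes, 1 rose and 7 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.00608; adjusted p = 0.429 with an estimated correlation), among them Mest at -1.54 and Oat at -1.22, which were possible free RNA. Secretory granule genes were mixed, with 4 higher and 3 lower of 19, and 5 and 3 adjusted over the list alone (camera adjusted p = 0.830). Scg2 and Scg3, granins of the granule, rose by 0.69 and 0.45, and Vamp2, a fusion protein, fell by 0.59.

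Of 21 immediate early and dissociation response genes, 0 rose and 20 fell at 16 v 8 weeks over all genes tested, and 21 fell adjusted over the list alone (camera adjusted p = 7.66e-15; adjusted p = 0.257 with an estimated correlation). Only 6 of the 21 were not possible free RNA, and all 6 fell. Hspa1a, an inducible heat shock protein, fell by 1.64 and Dusp1, a phosphatase of stress kinases, by 1.52 on the log2 scale. Of 26 genes of the unfolded protein response, 2 rose and 9 fell, and 3 and 12 adjusted over the list alone (camera adjusted p = 0.0261; adjusted p = 0.645 with an estimated correlation). Ddit3, a stress transcription factor, fell by 2.49 ± 0.17 and Hspa5, the main chaperone of the endoplasmic reticulum, by 0.66, whereas Atf6, a stress sensor, rose by 0.80 ± 0.13. Of 30 nuclear-encoded genes of oxidative phosphorylation, 1 rose and 10 fell, and 1 and 11 adjusted over the list alone (camera adjusted p = 0.00109; adjusted p = 0.595 with an estimated correlation), with Uqcrb at -0.55 and Cox4i1 at -0.43. Of 16 genes of oxidative stress, 0 rose and 6 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.00936; adjusted p = 0.429 with an estimated correlation), including Gpx1, a glutathione peroxidase, at -0.98 ± 0.16 and Prdx1, a peroxiredoxin, at -0.58. Of 18 cholesterol synthesis genes, 0 rose and 7 fell, and 8 fell adjusted over the list alone (camera adjusted p = 0.00411; adjusted p = 0.559 with an estimated correlation), with Fdps at -1.43 and Msmo1 at -1.15.

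Among the largest rises at 16 v 8 weeks were Hist2h2aa1, a histone gene that shares its 3′ end with another gene (3.63 ± 0.26), Slx1b (1.98 ± 0.23), Prpf4b, a splicing kinase (1.70 ± 0.14), and Pclo, a protein of the active zone (1.46 ± 0.15). Cdkn1b, which encodes the cell cycle inhibitor p27, rose by 1.20 ± 0.13 and Atm, a DNA damage kinase, by 1.47 ± 0.21. Dusp5, a phosphatase of ERK, fell by 2.33 ± 0.14, Lmna, a nuclear lamin, by 2.20, and Btg2, an antiproliferative p53 target, by 2.18. Of 24 p53 targets and DNA damage response genes, 5 rose and 8 fell, and 5 and 9 adjusted over the list alone (camera adjusted p = 0.177). Acinar markers were higher, 15 of 16, also adjusted over the list alone (camera adjusted p = 5.27e-11; adjusted p = 0.429 with an estimated correlation), and endothelial and stromal markers lower, 12 of 14, and 14 adjusted over the list alone (camera adjusted p = 4.63e-07; adjusted p = 0.429 with an estimated correlation). Transcripts of other cell types in the beta-like sums thus moved with age. Of the 3267 genes, 810 were possible free RNA. Library groups did not overlap for 42.0% of genes tested, against 10% by chance, and with each cell thinned to 14000 UMIs the count was 1966.

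At 14 weeks, beta-like cells already had lower immediate early and stress transcripts than at 8 weeks, and granule transcripts went both ways. As a list, the immediate early genes did not pass with an estimated correlation (adjusted p = 0.257). Of 11612 genes, 333 were higher and 641 lower. Nr4a1 fell by 2.96 ± 0.19 on the log2 scale (SE), Dusp5 by 1.92 ± 0.14, Ddit3 by 1.82 ± 0.17 and Dnajb1 by 1.76 ± 0.15. Chgb, a granin, rose by 0.83 ± 0.15, from 570.2 ± 48.1 to 1010.3 ± 175 CPM (SD, n = 3). Iapp, the amylin co-secreted with insulin, rose by 0.70 ± 0.16 (adjusted p = 0.0303), Scg5 by 0.50 ± 0.11 and Resp18 by 0.38 ± 0.10. Syt4, a synaptotagmin, fell by 0.93, Ptprn, a granule membrane protein, by 0.61 and Vamp2 by 0.53. Of 19 secretory granule genes, 3 were higher and 3 lower, and 5 and 4 adjusted over the list alone (camera adjusted p = 0.539). Immediate early genes had 0 higher and 15 lower of 21 (camera adjusted p = 5.27e-11; adjusted p = 0.257 with an estimated correlation), and 15 lower adjusted over the list alone. Only 6 of the 21 were not possible free RNA. Acinar markers had 6 higher of 16, and 15 adjusted over the list alone (camera adjusted p = 1.72e-12; adjusted p = 0.429 with an estimated correlation), with a median log2 change of 2.62, and 293 of the 974 genes were possible free RNA. Of 13 mitochondrially encoded transcripts, 13 had a log2 change below 0, while 0 passed with edgeR over all genes and 10 were lower adjusted over the list alone (camera adjusted p = 9.25e-06; adjusted p = 0.479 with an estimated correlation), 11 had an unadjusted p under 0.05, and DESeq2 called 9 and limma-voom 0.

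Cholesterol synthesis genes at 14 v 8 weeks had 0 higher and 6 lower of 18, and 11 lower adjusted over the list alone (camera adjusted p = 5.89e-05; adjusted p = 0.479 with an estimated correlation). Cyp51, a demethylase of sterol synthesis, fell by 1.03, Lss, which closes the sterol rings, by 1.02 and Insig1, a brake on this pathway, by 1.69. Hspa5 fell by 0.74 ± 0.11. Ccng1 and Bax, p53 targets, rose by 0.76 and 0.40, while Gadd45a fell by 0.72. Among list tests, the p53 targets and DNA damage response genes gave 3 higher and 4 lower of 24, and 3 and 5 adjusted over the list alone (camera adjusted p = 0.957). The count of 974 was 310 without library A at 14 weeks, 331 without 14 weeks B, 341 without 8 weeks B, 314 without 8 weeks C and 1539 without 16 weeks A. It was 596 with cells thinned and 589 with equal cell numbers, and groups did not overlap for 31.2% of genes, against 10% by chance.

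Between 14 and 16 weeks, beta cell identity genes rose, nuclear-encoded genes of oxidative phosphorylation fell and markers of several other cell types fell in beta-like cells, though no list passed with an estimated correlation. Of 11612 genes, 2338 were higher and 2174 lower at 16 weeks. Identity genes had 17 higher and 1 lower of 23 (camera adjusted p = 5.89e-05; adjusted p = 0.429 with an estimated correlation), and 19 higher and 1 lower adjusted over the list alone. Mafa rose from 0.245 to 1.75 CPM (adjusted p = 0.00024), and Slc2a2 rose by 1.23 ± 0.18 on the log2 scale (SE), Nkx6-1 by 0.69, Pdx1 by 0.53 and Ins1 by 0.32 ± 0.06. Iapp fell by 0.97 ± 0.16. Nuclear-encoded genes of oxidative phosphorylation had 1 higher and 23 lower of 30, the same numbers adjusted over the list alone (camera adjusted p = 7.20e-06; adjusted p = 0.516 with an estimated correlation), including Uqcrb at -0.64, Sdhb at -0.63 and Cox5a at -0.59. Of 13 mitochondrially encoded transcripts, 5 rose and 0 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.208), and mt-Nd6 at 1.82 and mt-Nd4l at 1.66 were among the largest rises. Cycs, cytochrome c, fell by 1.02 ± 0.19 and Bax by 0.81 ± 0.10. Chga and Scg3 rose by 0.58 and 0.66, whereas Resp18 fell by 0.76 and Scg5 by 0.67. Endothelial and stromal markers had 11 lower of 14, and 13 adjusted over the list alone (camera adjusted p = 1.62e-06; adjusted p = 0.429 with an estimated correlation), extracellular matrix genes 16 of 16 by both (camera adjusted p = 9.72e-08; adjusted p = 0.453), immune markers 4 of 14 by both (camera adjusted p = 0.000256; adjusted p = 0.479) and hormones of other islet cells 3 of 6 by both (camera adjusted p = 0.00782; adjusted p = 0.479), while 1 of 16 acinar markers was higher by both (camera adjusted p = 0.00608; adjusted p = 0.656). RNA of several other cell types thus fell as identity genes rose. Of the 4512 genes, 1043 were possible free RNA. The count was 2916 without 14 weeks B and 2942 with equal cell numbers, and groups did not overlap for 53.4% of genes, against 10% by chance.

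Cdkn1a, Cdkn2a and Bcl2 did not pass the test between ages in beta-like cells over all 9 libraries, while other genes of senescence lists did. Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 44.2 ± 6.27, 81.5 ± 18.4 and 55.0 ± 36.3 CPM at 8, 14 and 16 weeks (SD, n = 3). Its log2 change was 0.89 ± 0.57 at 14 v 8 weeks (SE; adjusted p = 0.381) and 0.34 ± 0.56 at 16 v 8 weeks (adjusted p = 0.705). These values rest on single libraries. Without 16 weeks A, which stood at 16.2 CPM against 60.9 and 88.0 CPM in B and C, the change at 14 v 8 weeks was 0.89 and passed (adjusted p = 0.0457) and that at 16 v 8 weeks was 0.76 (adjusted p = 0.0612), while without 16 weeks C the latter was -0.16. Cdkn2a, the p16 locus, changed by 1.34 ± 0.62 (adjusted p = 0.195) and 1.45 ± 0.60 (adjusted p = 0.0893) and was possible free RNA. Bcl2, a survival factor, changed by 0.56 (adjusted p = 0.392) and -0.07 (adjusted p = 0.916). Of 14 genes of senescence and survival, 1 rose and 3 fell at 16 v 8 weeks, the same numbers adjusted over the list alone (camera adjusted p = 0.579), with Cdkn1b higher and Plaur at -4.09, Gdf15 at -1.32 and Mcl1 at -0.46, which were possible free RNA. At 16 v 14 weeks 1 rose and 3 fell, and 1 and 2 adjusted over the list alone (camera adjusted p = 0.155), and at 14 v 8 weeks Plaur fell by 2.66. Of 21 genes of the senescence-associated secretory phenotype, 0 rose and 11 fell at 16 v 8 weeks, and 1 and 13 adjusted over the list alone (camera adjusted p = 2.79e-05; adjusted p = 0.429 with an estimated correlation). Il6 at -3.39, Cxcl2 at -4.58, Igfbp3 at -1.87 and Mmp2 at -1.07 were among them, each possible free RNA, since other classes held far higher levels.

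Interferon response and MHC class I genes varied between libraries of an age. B2m, the light chain of MHC class I, stood at 1104, 956 and 150 CPM in libraries A, B and C at 8 weeks, at 5254, 5411 and 3019 CPM at 14 weeks, and at 101, 1715 and 2594 CPM at 16 weeks. At 14 v 8 weeks, B2m changed by 2.63 ± 1.22 (SE; adjusted p = 0.239), H2-K1 by 2.19 ± 0.99 (adjusted p = 0.230) and Cd274, which encodes PD-L1, by 2.14 ± 0.76 (adjusted p = 0.144). Of 34 interferon response genes, 0 passed with edgeR over all genes and 0 adjusted over the list alone, while 11 had an unadjusted p under 0.05, and DESeq2 called 4 and limma-voom 0. Their median log2 change was 1.97 (camera adjusted p = 2.78e-07; adjusted p = 0.559 with an estimated correlation). Of 17 MHC class I genes 0 passed with each of the 3 tools, and 5 had an unadjusted p under 0.05. At 16 v 14 weeks 4 interferon response genes passed with each of the 3 tools, lower with edgeR, and 0 adjusted over the list alone, while 6 had an unadjusted p under 0.05 and 34 of 34 had a log2 change below 0 (camera adjusted p = 5.89e-05; adjusted p = 0.645 with an estimated correlation). Ifi35 was at -0.94 and Usp18 at -1.21. At 16 v 8 weeks 0 of 34 passed with each of the 3 tools, and 1 had an unadjusted p under 0.05. Immune markers in beta-like sums had 3 higher of 14 at 14 v 8 weeks, and 7 adjusted over the list alone (camera adjusted p = 1.62e-06; adjusted p = 0.429 with an estimated correlation).

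The share of beta-like cells with a Cdkn1a UMI, after thinning to 14000 UMIs, was 37.8% ± 3.15, 47.8% ± 8.82 and 32.4% ± 17.4 at 8, 14 and 16 weeks (SD, n = 3; p = 0.379, 2-sided exact permutation test; adjusted p = 0.568). For Cdkn2a it was 0.721% ± 0.290, 2.27% ± 0.709 and 1.36% ± 1.47 (exact permutation p = 0.325; adjusted p = 0.568), and for Bcl2 2.12% ± 1.98, 3.48% ± 1.72 and 2.13% ± 0.709 (exact permutation p = 0.629). Both rest on few cells. A Cdkn2a UMI was found in 2, 1 and 1 cells at 8 weeks, 21, 9 and 5 at 14 weeks and 0, 7 and 20 at 16 weeks in A, B and C. A Bcl2 UMI was found in 8, 0 and 6, in 21, 13 and 11 and in 7, 8 and 18 cells. Without thinning, the means were 60.3%, 64.1% and 50.04% for Cdkn1a, 1.60%, 3.92% and 5.02% for Cdkn2a, and 4.78%, 7.15% and 5.12% for Bcl2. Thinning left out 14, 23 and 28 cells at 8 weeks, 120, 47 and 43 at 14 weeks, and 37, 19 and 15 at 16 weeks in A, B and C. At 4000 UMIs, the Cdkn1a share was 14.8%, 25.2% and 16.6% in beta-like cells (median depth 33532, 31292 and 42506 UMIs) and 19.3%, 10.4% and 8.47% in alpha-like cells (8930, 10557 and 10456 UMIs). It was 16.7%, 9.32% and 6.57% in delta-like and 15.5%, 9.76% and 5.12% in gamma-like cells. In ductal-like cells it was 76.4%, 53.4% and 55.7%, in endothelial-like 92.0%, 48.7% and 58.3% and in pericyte-like 77.1%, 38.7% and 33.1%. Free RNA from such classes was thus not excluded as a source of Cdkn1a UMIs in beta-like cells. Cdkn2a was found in 0.156%, 0.743% and 0.243% of beta-like and 0.173%, 0.754% and 0.403% of alpha-like cells, but in 0.139%, 0.0459% and 0.0490% of delta-like cells and in 0 of 483, 410 and 391 gamma-like cells, so whether its share in beta-like cells is background stays open. Bcl2 was found in 1.40%, 0.629% and 0.788% of beta-like cells, below the 6.21%, 6.24% and 6.27% of alpha-like cells. However, Ins1 and Ins2 stood at 199760 and 388380 CPM in beta-like cells with a Cdkn1a UMI and at 230150 and 440610 CPM without. Much of the 4000 UMIs of a beta-like cell was thus insulin. Shares at 4000 UMIs, which also pool cells over libraries, are therefore not directly comparable between classes. Cdkn1a and Bcl2 fell in the same cell 34 times, against 39.2 by independence (mean log2 ratio -0.38 ± 1.03, SD, n = 9; above 0 in 2 of 9 libraries; exact sign-flip permutation p = 0.305).

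Beta-like cells with a Cdkn1a UMI had higher transcripts of p53 targets than cells of the same library without, and lower transcripts of insulin genes in part through the choice of cells. Of 7639 genes, 111 were higher and 98 lower. Of 21 p53 targets and DNA damage response genes, 10 were higher and 0 lower, and 10 adjusted over the list alone. Ccng1, a cyclin-like p53 target, was higher by 1.06 ± 0.09 on the log2 scale (SE; adjusted p = 2.61e-15; 9 of 9 libraries), Sesn2, a stress sensor, by 0.96 (9 of 9) and Bax, an activator of apoptosis, by 0.45 ± 0.06 (8 of 9). Phlda3, a p53 target and possible free RNA, was higher by 1.81 ± 0.14. Ins1 had a log2 difference of -0.20 ± 0.02 (adjusted p = 2.18e-09) and Ins2 of -0.19 (adjusted p = 2.67e-07), each lower in 9 of 9 libraries. A cell with less insulin leaves more of its 14000 UMIs to Cdkn1a, so this choice of cells itself lowers insulin. With each cell thinned to 5500 UMIs other than insulin, Ins1 was at -0.10 ± 0.03 (adjusted p = 0.0110) and Ins2 at -0.09 ± 0.03 (adjusted p = 0.0483), each higher in 1 of 9 libraries. In this setting 9 of 21 p53 targets and DNA damage response genes were higher, also adjusted over the list alone. Here 4 of 22 identity genes were lower (8 lower and 1 higher adjusted over the list alone). Trpm5, a channel in insulin release, was at -0.58 and Slc30a8, the zinc transporter of the granule, at -0.34 (-0.46, adjusted p = 0.101, and -0.22, adjusted p = 0.0207, with 5500 UMIs other than insulin), and 9 of 22 identity genes were lower and 0 higher (10 lower and 2 higher adjusted over the list alone). Of 28 interferon response genes, 13 were higher and 0 lower (21 higher adjusted over the list alone), including Irf1 at 0.46 (7 of 9 libraries) and Cd274 at 0.62 (8 of 9), and of 16 MHC class I genes 6 were higher, and 14 adjusted over the list alone. B2m differed by 0.19 (adjusted p = 0.643). With 5500 UMIs other than insulin, 16 of 29 interferon response genes (23 adjusted over the list alone) and 6 of 16 MHC class I genes (12 adjusted over the list alone) were higher, with Irf1 at 0.39 (6 of 9 libraries), Cd274 at 0.56 (5 of 9) and B2m at 0.16 (5 of 9; adjusted p = 0.771), so the direction was not shared by all libraries. Immediate early and dissociation response genes were higher, 6 of 21, and 12 adjusted over the list alone (8 and 13 with 5500 UMIs other than insulin). Among them Klf2, Klf4, Fos and Junb were possible free RNA. Acinar markers were lower, 8 of 15, and 14 adjusted over the list alone, as were mitochondrially encoded transcripts, 7 of 13, and 11 adjusted over the list alone, but their median log2 differences of -0.23 and -0.16 became -0.04 and -0.07 with 5500 UMIs other than insulin. Signs of stress or handling thus went with the split. Cells were chosen by the transcript, so Cdkn1a was left out. The count of 209 was 135 without 14 weeks A, 61 with DESeq2 and 424 with at least 2 Cdkn1a UMIs. Swapping the labels with and without a Cdkn1a UMI in part of the libraries gave up to 220.

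In other classes the question was whether changes in beta-like cells were shared. Cdkn1a fell in alpha-like cells by 0.95 ± 0.18 at 14 v 8 weeks and 1.54 ± 0.19 at 16 v 8 weeks on the log2 scale (SE; adjusted p = 0.00874 and 0.000107). It fell in delta-like cells by 0.84 and 1.52, gamma-like cells by 0.88 and 1.66, ductal-like cells by 1.52 and 1.46, endothelial-like cells by 2.19 and 1.94, and pericyte-like cells by 2.15 and 1.97. In fibroblast-like cells its log2 changes of -0.90 and -0.90 did not pass (adjusted p = 0.173 and 0.0919). The difference between beta-like and alpha-like cells in the 16 v 8 week change of Cdkn1a was 1.65 ± 0.53 and did not pass (adjusted p = 0.218). At 16 v 8 weeks 4517 of 12461 genes passed in alpha-like, 4594 of 12390 in delta-like, 2018 of 8521 in gamma-like, 4520 of 12143 in ductal-like, 1126 of 8157 in endothelial-like, 710 of 5337 in pericyte-like and 3004 of 11796 in fibroblast-like cells. The gamma-like count was 1202 without 16 weeks A. The endothelial-like count was 516 without 8 weeks B and 608 without 16 weeks B, and the pericyte-like count 266 without 16 weeks A, 300 without 8 weeks B, 324 without 16 weeks B and 397 without 8 weeks A. At 14 v 8 weeks 1405, 1181, 260, 2491, 837, 138 and 447 genes passed in the same order.

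**Figure D2:**
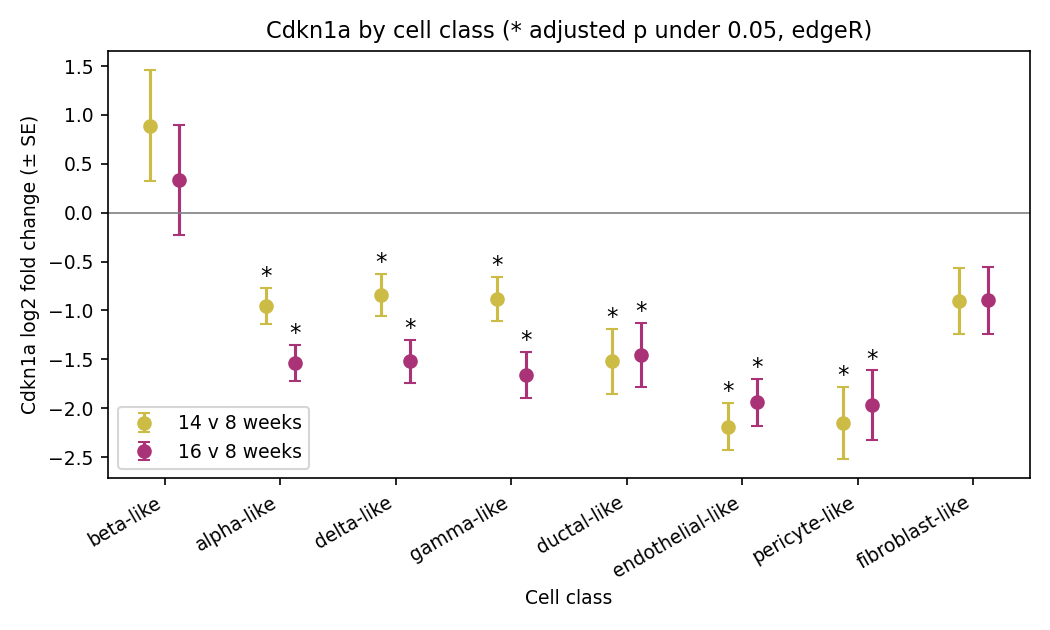
Log2 change of Cdkn1a with its standard error at 14 v 8 and 16 v 8 weeks in beta-like cells and 7 other classes, with an asterisk where the adjusted p was under 0.05. The change was -1.54 in alpha-like cells and 0.34 in beta-like cells at 16 v 8 weeks, where it was 0.76 without 16 weeks A and -0.16 without 16 weeks C. Free RNA was not excluded as a source of part of the falls in alpha-like, delta-like and gamma-like cells.

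Cholesterol synthesis genes fell in several classes. In alpha-like cells 15 of 18 fell at 14 v 8 weeks, and 16 adjusted over the list alone (camera adjusted p = 3.40e-10; adjusted p = 0.473 with an estimated correlation) and 17 of 18 at 16 v 8 weeks (camera adjusted p = 1.75e-08; adjusted p = 0.473 with an estimated correlation). In delta-like cells 11 of 17 fell at both, and 13 and 11 adjusted over the list alone (camera adjusted p = 1.75e-06 and 0.000126; adjusted p = 0.443 and 0.469 with an estimated correlation). In endothelial-like cells proliferation genes rose, 13 of 19 at 14 v 8 weeks and 1 fell (camera adjusted p = 4.52e-07; adjusted p = 0.481 with an estimated correlation; 15 rose adjusted over the list alone). Cenpf, a centromere protein, rose by 3.87 ± 0.61 and Ube2c, a mitotic ubiquitin ligase component, by 3.14, whereas Pcna, a replication clamp, fell by 2.88 at 16 v 8 weeks. The make-up of this class differed by age. Cluster 39, led by cell cycle genes, had 4, 27 and 20 cells at 8, 14 and 16 weeks and cluster 25, led by Glycam1, 21, 220 and 52, of 415, 456 and 350 endothelial-like cells, so the rise can come from the share of cycling cells. Errfi1, a brake on epidermal growth factor signalling, fell in delta-like cells by 1.98 at 14 v 8 weeks. Neurog3, a factor of endocrine progenitors, rose in delta-like cells by 1.14 ± 0.15 and 1.52 ± 0.15. In ductal-like cells Ccl2, a monocyte chemokine, fell by 4.84 and in fibroblast-like cells by 4.28 at 16 v 8 weeks. These classes too held different clusters by age. Ductal-like cluster 14 had 661 cells at 8 weeks and 0 at 16 weeks, fibroblast-like cluster 10, with Ccl2 among its leading genes, 861 and 102, and fibroblast-like cluster 13, 2 and 651. Mt1, a metallothionein, fell by 3.17 in alpha-like cells. Across these classes 171 list calls were made by camera with the preset correlation and 0 with an estimated one.

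The change between 8 and 16 weeks differed between beta-like and alpha-like cells for 383 of 12840 genes, 186 higher and 197 lower in beta-like cells. The change of immediate early and stress genes was lower in beta-like cells for 15 of 21 over all genes and 19 adjusted over the list alone, with a median difference of -1.94. Of the 15, 11 had a log2 change above 0 in alpha-like cells, 2 of them past the threshold, and 4 one below 0. Only 6 of the 21 were not possible free RNA in beta-like cells. Dusp1 changed by -1.52 in beta-like and 1.16 in alpha-like cells, a difference of -2.59 ± 0.12 (SE; adjusted p = 4.5e-14). Hspa1a differed by -3.03 ± 0.51 (adjusted p = 0.0370), Dnajb1 by -2.69 ± 0.45 (adjusted p = 0.0357), and Rasd1, a Ras-like protein induced by steroids, by -3.66 ± 0.16. Cholesterol synthesis genes fell less in beta-like cells, 8 of 18 over all genes and 11 adjusted over the list alone, with Msmo1 differing by 1.49 ± 0.14 (-1.15 in beta-like and -2.66 in alpha-like cells). Iapp differed by 1.10 ± 0.19. The count was 185 without 8 weeks C, 216 without 8 weeks B and 217 without 16 weeks B, and 208 with DESeq2.

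**Figure D3:**
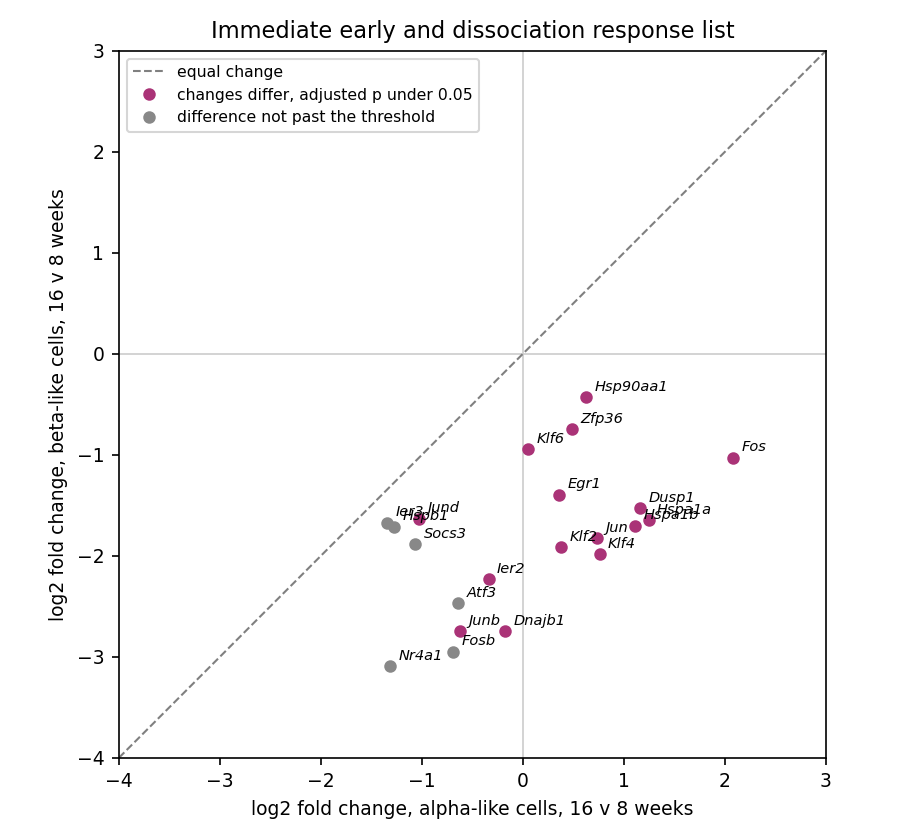
Log2 change at 16 v 8 weeks of 21 immediate early genes in alpha-like cells (x axis) and beta-like cells (y axis), with a point per gene coloured by whether the difference between classes had an adjusted p under 0.05 and a dashed line of equal change. The difference passed for 15 of 21 genes, for example Dusp1 at -1.52 in beta-like and 1.16 in alpha-like cells. Only 6 of the 21 were not possible free RNA in beta-like cells.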

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

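The tests of depth, of batches, of free RNA and handling for stress genes, and of a wrong age label were chosen after the result was seen, while those of shared 3′ ends, of immune RNA and of other splits of the libraries were chosen before. The change between 8 and 16 weeks differed between beta-like and alpha-like cells, by a test of the difference itself, for 383 genes. The named differences on the log2 scale were 1.49 for Msmo1, 1.24 for Spock1, 1.19 for Abracl, 1.17 for Pdyn and 1.10 for Iapp. They were -3.66 for Rasd1, -3.22 for Fos, -3.03 for Hspa1a, -2.81 for Hspa1b and -2.69 for Dnajb1. The 10 splits of 6 libraries are too few for a share under 0.05. The real split, counted as 1, gave 383 genes and the highest other 45.

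Many genes differed between 16 weeks and the earlier ages in beta-like cells. Of those past the threshold at 16 v 14 weeks with a position, 3.38% shared their 3′ end with another gene (152 of 4502, exact interval 2.87% to 3.95%). Of the others, 1.86% did (132 of 7091). So few genes share a 3′ end that a large share could not arise. Shared reads can thus be at most a part of the cause. Such a part stays open, since the share was 6.45% among genes past the threshold and changed at least 2-fold. At 16 v 8 weeks it was 3.56% of genes past the threshold against 2.02% of the others, but 1.44% against 2.54% at 14 v 8 weeks. With each cell at the same depth 69.5% passed again with the same sign, and 56.5% at 16 v 8 weeks, which argues against depth as the whole cause. The labels name 0 batches, so a batch of the 16-week libraries and age cannot be told apart. Age itself stays open and untested.

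Immediate early and stress genes were higher in beta-like cells at 8 weeks. The 6 members not counted as possible free RNA, Dusp1, Nr4a1, Hspa1a, Hspa1b, Dnajb1 and Hsp90aa1, were all lower at 16 weeks. That rule uses levels pooled over ages, and free RNA that became rarer would fall too. This fall thus cannot decide whether free RNA was their source. Of the 15 others, 2, Fosb and Klf2, fell by more CPM than their level in alpha-like cells at 8 weeks. However, the median depth at 8 weeks was 33532 UMIs in beta-like and 8930 UMIs in alpha-like cells. The same free RNA would thus give fewer CPM in a beta-like cell, and the alpha-like level is too high a limit. This comparison cannot decide whether free RNA was the source of the 15, and free RNA was not excluded. The change was lower in beta-like than in alpha-like cells for 15 of 21 members, of which 11 had a log2 change above 0 in alpha-like cells, which argues against handling that acts alike on all classes. The median mitochondrial share of cells fell with age too, at 3.60%, 3.51% and 5.02% at 8 weeks, 3.19%, 3.03% and 3.32% at 14 weeks and 2.65%, 2.15% and 2.11% at 16 weeks, and 233 cells of 8 weeks C were over 20%. A difference in cell quality or handling that acts more on beta cells thus stays open and may account for the pattern, and age stays open.

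Interferon response and MHC class I genes differed between libraries of an age. Immune RNA brought at most 2.56% of the B2m of a beta-like sum, in 8 weeks C, which argues against immune cells as its source. In 16 weeks A, 13.8% of genes called without it lay nearer the 8-week mean, against 80.2% to 88.8% in 8-week libraries and 6.42% and 12.5% in 16 weeks B and C, which argues against an 8-week library under a wrong label. A difference between animals in the stage of islet inflammation may account for the pattern and was not tested, since the labels name no animals.

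For any age in beta-like cells, 1 of 100 splits of the libraries gave as many genes as the real 5078, the real split itself, and the highest other gave 1999. Only 100 of the 280 splits were run, so this makes chance unlikely but does not exclude it. For beta-like cells with against without a Cdkn1a UMI, libraries were not regrouped. The labels with and without were instead swapped within drawn sets of libraries. Of 100 such labellings, the real one included, 2 gave as many as the real 209, and the highest other gave 220. A swap in few libraries leaves the labels of the rest as they were, so these labellings differ in kind from the splits by age. The 10 splits of 2 ages are too few for a share under 0.05 in each class. In beta-like cells the real splits gave 974, 3267 and 4512 genes and the highest other 0 each. At 14 v 8 weeks the real and highest other counts were 1405 and 0 in alpha-like, 1181 and 1 in delta-like, 260 and 0 in gamma-like, 2491 and 0 in ductal-like, 837 and 0 in endothelial-like, 138 and 6 in pericyte-like and 447 and 0 in fibroblast-like cells. At 16 v 8 weeks they were 4517 and 1, 4594 and 0, 2018 and 4, 4520 and 0, 1126 and 0, 710 and 8, and 3004 and 0 in the same order.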

How the results depend on the processing

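The alternatives of doublets at the expected rate, of 16 weeks A and 8 weeks C left out together, of genes with shared 3′ ends left out and of cells thinned to a number of UMIs other than insulin were tests chosen after the result was seen. Of 6644 values of named genes that passed in beta-like cells, 6122 kept direction and side of the threshold, 522 kept direction only and 0 reversed. Except where a smaller number of libraries, cells, UMIs or genes shows it, the cause was not tested.

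Genes past the threshold in beta-like cells numbered 1440 for any age, 351 at 14 v 8, 1017 at 16 v 8 and 1280 at 16 v 14 weeks with a mean of at least 20 CPM required, which tests fewer genes. With thinned cells they numbered 596 and 1966 at 14 v 8 and 16 v 8 weeks, of which 474 and 1847 were shared with the counts from all UMIs. With 152 cells per library they numbered 589 at 14 v 8 and 2942 at 16 v 14 weeks. Libraries of the same replicate letter did not deviate together from the means of their ages, with same-letter correlations from -0.437 to 0.213. With 3 libraries per age, this cannot show whether the letters mark something shared between ages. With the letter as a block, 528 genes passed at 14 v 8 weeks in beta-like cells and, at 16 v 8 weeks, 692 in endothelial-like and 386 in pericyte-like cells. DESeq2 gave 1003 in gamma-like cells, 445 in pericyte-like cells, 208 for the interaction and 61 for the Cdkn1a comparison. No filter on counts gave 1169 in pericyte-like cells, and at least 2 Cdkn1a UMIs gave 424 genes. Lists called numbered 48 of 84 with the preset correlation, 0 with an estimated one and 34 with fry.

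With each library left out in turn, counts ran from 3636 to 5274 for any age, 310 to 1539 at 14 v 8, 2407 to 3189 at 16 v 8 and 2916 to 4875 at 16 v 14 weeks in beta-like cells. At 16 v 8 weeks they ran from 1202 to 2179 in gamma-like, 516 to 1254 in endothelial-like and 266 to 885 in pericyte-like cells. They ran from 185 to 558 for the interaction and 135 to 249 for the Cdkn1a comparison. The mean log2 ratio of Cdkn1a and Bcl2 in the same cells ran from -0.59 without 16 weeks A (exact permutation p = 0.0469) to -0.12. Pericyte-like cells with at least 50 cells per library were not run, since too few libraries were left.

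Values on the log2 scale that changed sign were of genes that had not passed. At 14 v 8 weeks thinning gave Mmp2 0.085 and Ins1 0.0083, and the looser cell filter gave Ins1 0.0039. At 16 v 8 weeks limma-voom gave Bcl2 0.013 and Cxcl10 -0.40, and Ins2 was at 0.0027 with no filter on counts, 0.13 with a mean of at least 20 CPM required and 0.015 with the looser cell filter. Without 16 weeks A and 8 weeks C, Bcl2 was at 0.21. Cdkn2a at 16 v 14 weeks was at -0.071 with DESeq2 and -0.13 with the block. With each library left out in turn, Mmp2 (14 v 8) ran from -0.50 to 0.21, and Cdkn2a (16 v 14) from -0.49 without 16 weeks C to 0.38. At 16 v 8 weeks Cdkn1a ran from -0.16 without 16 weeks C to 0.76 without 16 weeks A, Bcl2 from -0.37 to 0.18, Bcl2l1 from -0.12 to 0.21, Ins2 from -0.12 to 0.043 and Ucn3 from -0.54 to 0.0027. With fry, the list of p53 targets and DNA damage response genes (adjusted p = 0.940) changed direction at 14 v 8 weeks. So did glycolysis and endothelial and stromal markers (adjusted p = 0.987 each).

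The added alternatives gave 5034 genes for any age and 958 at 14 v 8 weeks with doublets at the expected rate, 4767 and 783 without 16 weeks A and 8 weeks C, and 4917 and 960 without genes with shared 3′ ends. Leaving out possible free RNA gave 3853 and 681. Cells thinned to 5500 UMIs other than insulin gave 171 genes in the Cdkn1a comparison. No class share and no share of cells with a UMI passed under any alternative run.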

Other observations

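The tests of the share of immune cells against gene levels were chosen after the result was seen, and the test of interferon genes in the same cells before. Hist2h2aa1, which shares its 3′ end with another gene, was higher at 16 than at 8 weeks in many classes. It rose by 3.63 in beta-like, 2.80 in alpha-like, 3.35 in delta-like, 2.37 in gamma-like, 2.72 in ductal-like and 3.60 in pericyte-like cells on the log2 scale. Batch and age cannot be told apart for this gene.

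Oxidative phosphorylation genes were lower at 16 than at 8 weeks outside beta-like cells as well, with 19 of 30 lower in alpha-like cells, and 23 adjusted over the list alone (camera adjusted p = 4.28e-05; adjusted p = 0.504 with an estimated correlation), 27 in delta-like cells, and 29 adjusted over the list alone (camera adjusted p = 1.39e-08; adjusted p = 0.443 with an estimated correlation) and 19 in fibroblast-like cells, and 21 adjusted over the list alone (camera adjusted p = 3.56e-07; adjusted p = 0.465 with an estimated correlation).

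Over the 9 libraries, the share of immune cells (log2 percent) went with the level in beta-like cells of B2m (r = 0.909, exact permutation p = 0.000496; rho = 0.817, exact permutation p = 0.0108) and Cdkn1a (r = 0.912, exact permutation p = 0.00054; rho = 0.867, exact permutation p = 0.00451). Without 8 weeks C and 16 weeks A, the 2 libraries farthest from the median share, r was 0.755 and 0.866. Adjusted over the 4 relations computed, p was 0.00108 for each. Ages are pooled here. With values centred by age, r was 0.871 for B2m (exact permutation p = 0.0556 over 216 orders within ages) and 0.910 for Cdkn1a (exact permutation p = 0.106), so neither relation passed within ages. At 14 weeks, library C had the most immune cells (6.40%) but the lowest B2m (3019 CPM) and Cdkn1a (61.4 CPM), with 3 libraries too few to test a relation. In addition, 13 interferon response genes were higher in beta-like cells with a Cdkn1a UMI, and 16 with cells thinned to 5500 UMIs other than insulin, though Irf1 in 6 and Cd274 in 5 of 9 libraries there. A candidate explanation is that Cdkn1a and interferon genes are found in the same beta cells, a hypothesis tested on the same data.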
